A study of Nannochloropsis oceanica with 12 samples.

How the data were processed

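The measurements were polyadenylated RNA levels in *Nannochloropsis oceanica* IMET1, a unicellular marine alga, in the wild type (WT) and in M2, an RNA interference line with reduced expression of the carbonic anhydrase CA2. Per the labels, cultures of both lines were moved to fresh medium under 5% CO2 and sampled after 12 h and 24 h, with 3 biological replicates in each of the 4 groups. The treatment text in the labels describes another layout, with a second CO2 level and more time points, and the groups used here follow the sample titles and the design text instead. Per the labels' protocols, polyadenylated RNA was fragmented and primed with random hexamers, and libraries were made without strand information and sequenced as read pairs. The labels name whole cells and total RNA as the source but also give nuclear RNA as the molecule subtype, so whether the values measure whole-cell or nuclear RNA is not settled. Without strand, reads of overlapping genes on opposite strands cannot be told apart.

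The authors deposited FPKM values, which are fragments scaled to transcript length and to the mapped total of a library, for 9756 genes, with 1 table for each of the 4 groups and 2 tables of merged group values. TopHat2 2.0.4 and Cufflinks 2.0.2 are named in the submitters' processing notes. The genome build, the gene annotation and whether the 4 tables were normalized together are not given in the sources used here. Because each group has a table of its own, every comparison sets values of different tables side by side, and a difference between tables and a difference between groups cannot be separated. FPKM values are not counts, so no count model was used, and the read depth of each library is unknown. Steps between low values gave the relative depth within groups: 1 read in M2 12 h replicate 1 was worth 4.08 times what it was worth in replicate 2, and in the 24 h groups these ratios lay between 0.91 and 1.08. For WT at 12 h this ratio was not estimated.

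All but 1 of the 9756 gene IDs name a scaffold and a number. The exception, isotig00738.DGAT1A, names no scaffold and carries a gene name. None of the IDs (0) matched the reference gene table used here, which holds only 160 organelle genes, so this says little about the deposited IDs. The ID of CA2 is not given in the labels, so the level of the targeted gene, and with it the knockdown, could not be checked. Gene lists for pathways, fixed by product name before the data were examined, could not be tested for the same reason.

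The last column of the M2 12 h table repeats the header of replicate 2. Its values equalled 0.724 times those of replicate 1, within 0.1%, for 9646 of the 9647 genes above 0, and the same genes were at 0 in both. The SD of the log2 ratio of these columns was 0.0029, against 0.0924 to 0.105 between 24 h replicates, so they differed by less than the noise between libraries and were counted as 1 library. This left 2 libraries for M2 at 12 h, 3 in each other group, and 11 in all. The merged columns were compared with the replicate columns and entered no test. The headers of the M2 24 h table write MT for M2, and its columns were assigned to M2 because the table is linked to that group.

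Each library was scaled by a median-of-ratios factor over the 9170 genes above 0 in all 12 columns. Genes with a mean FPKM of at least 1 were tested (9589 genes) on log2(scaled FPKM + 1), which understates the change of low genes. A mean per group was fitted to all 4 groups with limma 3.58.1 in R 4.3.3, with moderated statistics and an intensity trend, 2-sided, without a replicate block. P-values were adjusted by the Benjamini-Hochberg method in each of 5 comparisons, with a threshold of 0.05: M2 against WT at 12 h and at 24 h, 24 h against 12 h in each line, and the interaction of line and time. Overlaps of called genes were tested with Fisher's exact test, 2-sided, and principal components were computed from gene-centred log2 values. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

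The test, its filter, the scaling, most alternatives and the rule for named genes were set before the data were examined. By that rule, with IDs that carry no names, the 2 genes with the highest and the 2 with the lowest mean log2 change over both times were named, among genes past the threshold in the same direction at both times, with a mean FPKM of at least 5 in a compared group and replicate values that did not overlap. Diacylglycerol acyltransferase DGAT1A was named outside the rule, after the IDs were seen, since its ID alone carries a name. Alternatives covered pseudocounts of 0.1 and 5, other filters, 3 other scalings, the replicate number as a block, fits of the compared groups only, other moderation settings, a minimum fold of 2 and leaving out each library. After the data were seen, counts without WT 12 h replicate 3 were added for the comparisons that do not include it, along with weights per library and the repeated column as a library of its own.

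The fit was tested on simulated data with 100 of 9589 genes changed per fold size. For M2 against WT at 12 h it recovered 2% of 1.5-fold and 19% of 2-fold changes with all libraries, and 85% and 98% without WT 12 h replicate 3. For M2 against WT at 24 h it recovered 1% and 27% with all libraries, and 89% and 96% without that library. False calls were 0% to 3.6% of all calls. Deviations of the simulated WT 12 h replicate 3 had the same SD for all genes. The recovery with all libraries describes that setting and may not describe the data. Apart from the changed genes the simulated groups had a common mean per gene, noise was independent and normal, and no difference between tables was added. The share of false calls therefore says nothing about calls that such a difference gave in the data.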

Results

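The transcriptomes of wild-type (WT) *Nannochloropsis oceanica* IMET1 and of M2, an RNA interference line of the carbonic anhydrase CA2, were compared 12 h and 24 h after transfer to fresh medium under 5% CO2. Carbonic anhydrases interconvert CO2 and bicarbonate. The design asks how M2 differs from WT in transcript levels at high CO2, and how both lines change with time in culture. With a single knockdown line and no control line besides WT, an effect of lowered CA2 cannot be told apart from other differences between the lines. Of the 12 labelled libraries, 11 were distinct: 3 for WT at 12 h, 2 for M2 at 12 h, and 3 for each line at 24 h. Depth in reads is unknown, and FPKM sums per library lay between 606886 and 617319, except 780704 in WT 12 h replicate 3. The ID of CA2 is not given in the labels, so its level is not reported.

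WT 12 h replicate 3 stood apart from every other library. Its log2(FPKM + 1) values correlated across genes with those of its own group at r = 0.715 for both other replicates, whereas other within-group correlations were 0.992 to 0.997. In that library 148 genes were at 0 that had at least 10 FPKM in both other WT 12 h libraries. Over all genes with a mean FPKM of at least 1, on the scale of scaled FPKM + 1, 1012 lay at least 4-fold above and 792 at least 4-fold below the mean of those libraries, compared with 0 genes between replicates 1 and 2. Genes are not independent replicates, and these values describe libraries. The library was kept in the planned test, and each count below is also given without it.

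On principal component 1, which held 70.3% of the variance, WT 12 h replicate 3 had a score of 139.8 and every other library lay between -32.5 and -1.2. Without it, component 1 held 67.4% of the variance and component 2 held 17.7%. Along component 1 of that second analysis the groups were ordered M2 12 h (40.7 and 43.7), WT 12 h (17.5 and 18.3), M2 24 h (-11.7 to -11.5) and WT 24 h (-28.7 to -28.2). At each time M2 had higher scores than WT. Component 2 separated the lines, with M2 between -17.7 and -5 and WT between 9 and 17.9.

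**Figure D1:**
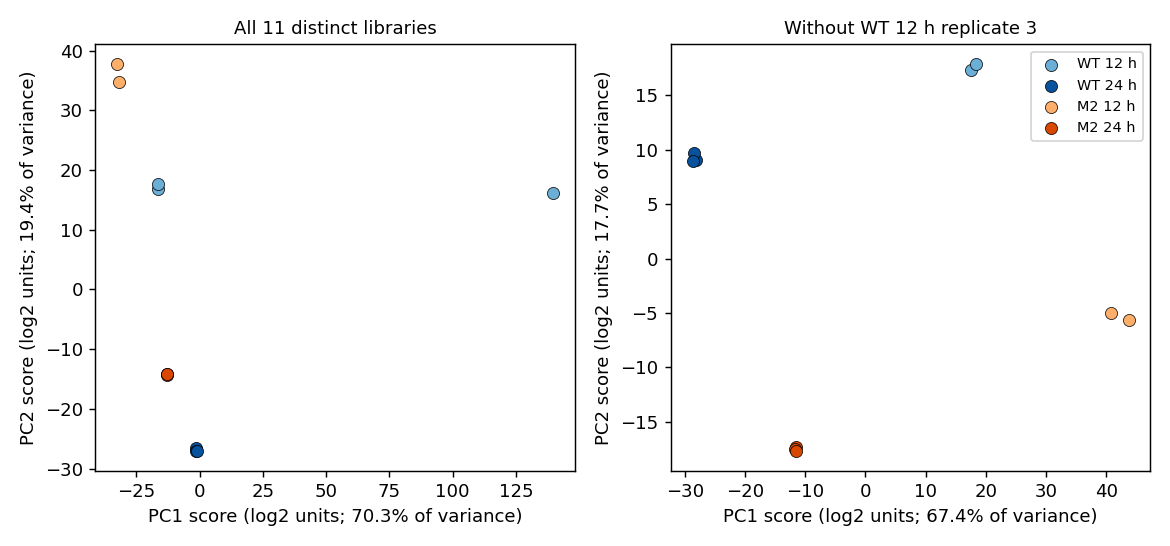
Scores of the libraries on principal components 1 and 2 (log2 units, 1 point per library, colours for the 4 groups), with all 11 libraries on the left and without WT 12 h replicate 3 on the right. On the left that library lies at 139.8 on component 1, and on the right the groups separate, with component 1 holding 67.4% of the variance.

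At 12 h, 294 genes were higher and 530 lower in M2 than in WT, of 9589 tested (limma, adjusted p under 0.05). Large changes were mostly decreases: 175 genes were lower and 14 higher by at least 2-fold. The deepest of the named falls was in scaffold00185.g5945, from 547 ± 360 scaled FPKM in WT (SD, n = 3) to 44.4 ± 3.48 in M2 (SD, n = 2), a log2 change of -3.41 (SE 0.39, limma adjusted p = 0.003). Scaffold00080.g2595 fell from 22.8 ± 13.6 (SD, n = 3) to 1.51 ± 0.639 (SD, n = 2), a log2 change of -3.13 (SE 0.4, limma adjusted p = 0.0047). Among increases, scaffold00341.g9771 rose from 165 ± 8.5 (SD, n = 3) to 376 ± 4.19 (SD, n = 2), a log2 change of 1.18 (SE 0.07, limma adjusted p = 0.00061), and scaffold00145.g5108 rose from 90.8 ± 9.85 (SD, n = 3) to 148 ± 8.04 (SD, n = 2), a log2 change of 0.70 (SE 0.14, limma adjusted p = 0.02).

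Much of the WT spread in the falling pair at 12 h lay in WT 12 h replicate 3, where scaffold00185.g5945 had 963 scaled FPKM against 342 and 337. Without it the log2 changes were -2.91 for scaffold00185.g5945 (SE 0.05), -2.69 for scaffold00080.g2595 (SE 0.2), 1.14 for scaffold00341.g9771 (SE 0.04) and 0.61 for scaffold00145.g5108 (SE 0.1), all past the threshold with limma. The median SE over all genes fell from 0.256 to 0.08, and 2763 genes were higher and 2714 lower, which included all 824 genes called with every library, in the same direction. At least 2-fold changes then numbered 21 higher and 221 lower. A fit of the 12 h libraries alone, replicate 3 included, called 0 genes with limma (661 at an unadjusted p under 0.05), so the named genes lost their calls there, and leaving out M2 replicate 1 or 2 gave 74 or 134 genes. With either M2 library left out scaffold00145.g5108 missed the threshold (log2 changes 0.64 and 0.75), as it did under each other scaling (0.77 to 0.9), and without M2 replicate 1 so did scaffold00080.g2595 (-2.87). Scaling moved the balance of directions, to 111 higher and 503 lower for FPKM as deposited and 45 higher and 337 lower with all libraries scaled to an equal sum.

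At 24 h, 211 genes were higher and 227 lower in M2 than in WT (limma, 3 libraries each), and at least 2-fold changes numbered 7 and 21. Scaffold00145.g5108 rose from 12.1 ± 1.23 scaled FPKM in WT (SD, n = 3) to 53.5 ± 5.8 in M2 (SD, n = 3), a log2 change of 2.05 (SE 0.12, limma adjusted p = 0.00023). For scaffold00341.g9771 the levels were 52.2 ± 1.63 and 149 ± 5.23 (SD, n = 3 each), a rise of 1.5 on the log2 scale (SE 0.07, limma adjusted p = 5.5e-05). Scaffold00185.g5945 fell from 240 ± 1.54 to 83.3 ± 1.51 (SD, n = 3 each), a log2 change of -1.51 (SE 0.35, limma adjusted p = 0.047), and scaffold00080.g2595 fell from 9.27 ± 0.548 to 2.07 ± 0.66 (SD, n = 3 each), a log2 change of -1.76 (SE 0.36, limma adjusted p = 0.029).

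The SEs of the 24 h comparison include the spread of WT 12 h replicate 3, because all groups shared 1 estimate of spread. Without that library 3072 genes were higher and 2475 lower at 24 h, including all 438 genes called with every library, and at least 2-fold changes numbered 18 and 84. The calls of scaffold00185.g5945 and scaffold00080.g2595 at 24 h were lost when any 1 of the 6 24 h libraries was left out while WT 12 h replicate 3 stayed in, which gave 103 to 121 genes in all, with log2 changes of -1.52 to -1.5 and -1.92 to -1.62. With a pseudocount of 5 scaffold00080.g2595 missed the threshold (-1.02), and with other moderation settings so did scaffold00185.g5945 (-1.51). A fit of the 24 h libraries alone called 6020 genes. FPKM as deposited gave 87 higher and 198 lower genes, and scaling to an equal sum gave 42 and 122.

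**Figure D2:**
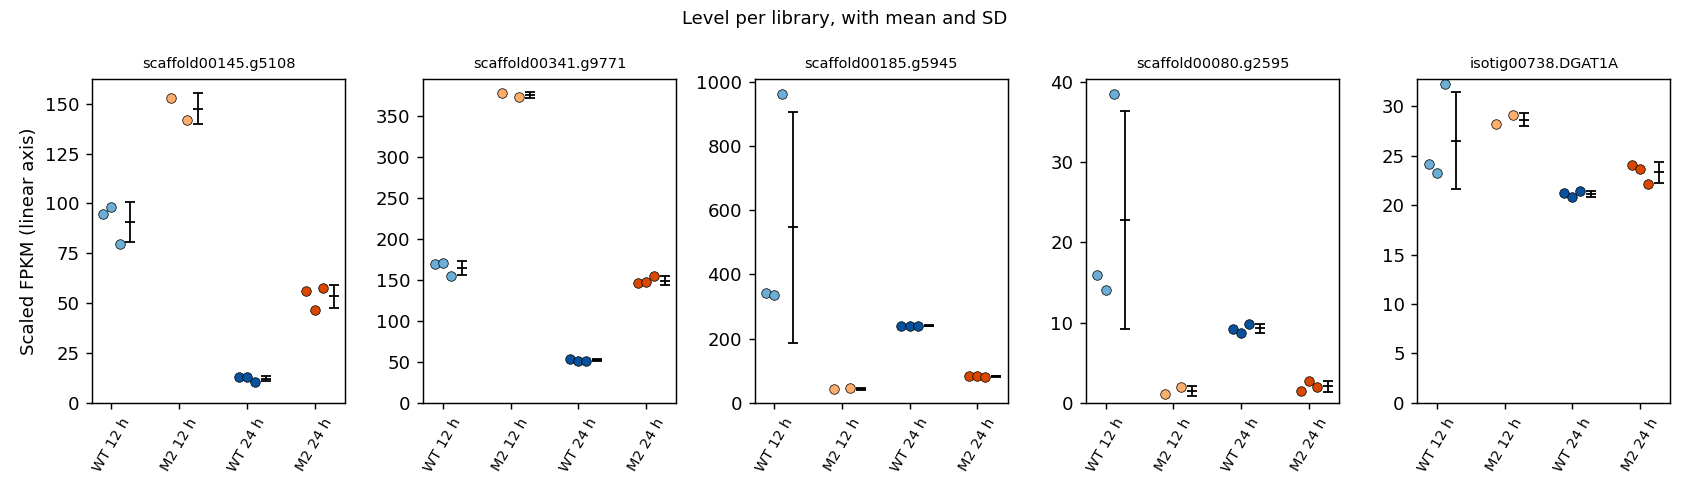
Scaled FPKM of the named genes in each library (linear axes from 0, 1 point per library, bars for the mean and SD of each group, n = 3, or n = 2 for M2 at 12 h). The high WT 12 h point in the panel of scaffold00185.g5945, at 963, is replicate 3.

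DGAT1A encodes a diacylglycerol acyltransferase, which makes triacylglycerol from diacylglycerol. It did not pass the threshold between the lines at either time with all libraries. Its levels at 12 h were 26.5 ± 4.95 scaled FPKM in WT (SD, n = 3) and 28.6 ± 0.629 in M2 (SD, n = 2), a log2 change of 0.12 (SE 0.14, limma adjusted p = 0.53). Levels at 24 h were 21.1 ± 0.309 in WT and 23.3 ± 1.06 in M2 (SD, n = 3 each), a log2 change of 0.13 (SE 0.13, limma adjusted p = 0.75). Without WT 12 h replicate 3 it passed at both times, with log2 changes of 0.26 at 12 h (limma adjusted p = 0.0035) and 0.13 at 24 h (limma adjusted p = 0.038).

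The line differences at 12 h and 24 h, which share no library, overlapped. Higher in M2 at both times were 76 genes, against 6.5 for independent lists (Fisher's exact test, 2-sided, p = 6e-63), and lower at both times were 124 genes, against 12.5 (Fisher's exact test, 2-sided, p = 2e-98). Another 9 genes passed at both times in opposite directions. Fold changes at the 2 times correlated across genes at Pearson r = 0.46 and Spearman rho = 0.44. Without WT 12 h replicate 3 the shared genes were 1603 higher and 1523 lower, against 885.2 and 700.5 for independent lists, with 602 genes in opposite directions and r = 0.51. Both lists come from 1 fit with a shared estimate of spread per gene, so genes of low spread are called in both more often than independent lists allow, and neither the excess nor its p-value measures a shared line effect. Genes are also not independent.

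Between 12 h and 24 h in WT, 720 genes rose and 808 fell (limma), of which 211 rose and 112 fell by at least 2-fold. Scaffold00145.g5108 and scaffold00341.g9771, both higher in M2, fell with time in WT, with log2 changes of -2.81 (SE 0.12, limma adjusted p = 1.3e-05) and -1.64 (SE 0.07, limma adjusted p = 8.5e-06). Of the pair lower in M2, scaffold00185.g5945 had a log2 change of -1 (SE 0.35, limma adjusted p = 0.09) and scaffold00080.g2595 one of -1.07 (SE 0.36, limma adjusted p = 0.078). Without WT 12 h replicate 3 both fell, at -0.5 (SE 0.04, limma adjusted p = 7.9e-07) and -0.64 (SE 0.18, limma adjusted p = 0.0093). In that fit 3247 genes rose and 3098 fell, including all 1528 called with every library, and the 2-fold counts were 347 and 157. A fit of the WT libraries alone, replicate 3 included, called 297 genes, and leaving out WT 24 h replicate 1, 2 or 3 gave 851, 861 or 873. With FPKM as deposited 765 rose and 442 fell, and with scaling to an equal sum 674 rose and 242 fell. These scalings moved the median log2 change of all genes by 0.136 and 0.246.

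In M2, 788 genes rose and 655 fell between 12 h and 24 h (limma), and 372 rose and 53 fell by at least 2-fold. The same named pair fell in M2, with log2 changes of -1.45 for scaffold00145.g5108 (SE 0.14, limma adjusted p = 0.00038) and -1.33 for scaffold00341.g9771 (SE 0.07, limma adjusted p = 3.6e-05). For scaffold00185.g5945 the log2 change was 0.9 (SE 0.39, limma adjusted p = 0.18, and 4.9e-09 without WT 12 h replicate 3), and for scaffold00080.g2595 it was 0.29 (SE 0.4, limma adjusted p = 0.74, and 0.18 without that library). Without WT 12 h replicate 3 in the shared estimate of spread, 3382 genes rose and 3321 fell, including all 1443 called with every library, and the 2-fold counts were 768 and 84. A fit of the M2 libraries alone called 6371 genes, and leaving out M2 12 h replicate 1 or 2 gave 533 or 617, and M2 24 h replicate 1, 2 or 3 gave 816, 812 or 824. With FPKM as deposited 825 rose and 338 fell, and with scaling to an equal sum 749 rose and 169 fell.

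Time changes in the lines, which also share no library, had 416 rises and 425 falls in common, against 59.2 and 55.2 for independent lists, with the same shared estimate of spread, and 5 genes went in opposite directions. Across genes the time changes correlated at Pearson r = 0.36 and Spearman rho = 0.32. Without WT 12 h replicate 3 there were 2445 shared rises and 2418 shared falls, against 1145.2 and 1072.9 for independent lists. In that fit 250 genes went in opposite directions, with r = 0.77.

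**Figure D3:**
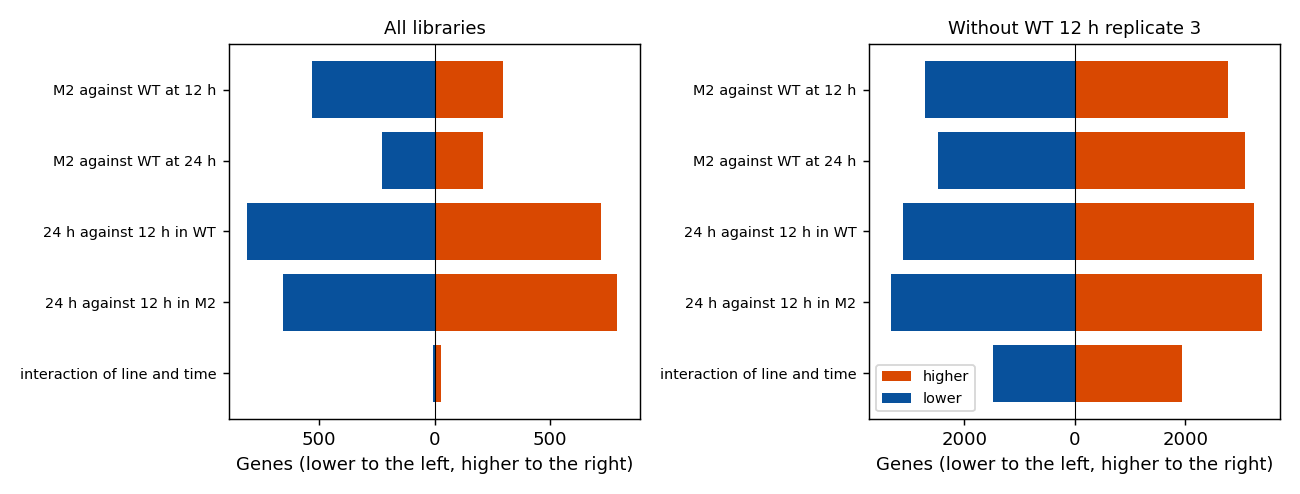
Numbers of genes higher (right of 0) and lower (left of 0) in each comparison at a limma adjusted p under 0.05, with all libraries on the left and without WT 12 h replicate 3 on the right, on axes of different range. For M2 against WT at 12 h the counts are 294 and 530 on the left and 2763 and 2714 on the right.

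The difference between the lines itself differed between 24 h and 12 h for 35 genes (limma, interaction of line and time), 28 with a higher and 7 with a lower log2 change at 24 h. Scaffold00145.g5108 was among them: its rise in M2 over WT was larger at 24 h by 1.35 on the log2 scale (SE 0.18, limma adjusted p = 0.032). For scaffold00341.g9771 the difference was 0.32 (SE 0.1, limma adjusted p = 0.27), for scaffold00185.g5945 it was 1.90 (SE 0.52, limma adjusted p = 0.21) and for scaffold00080.g2595 it was 1.37 (SE 0.53, limma adjusted p = 0.38). Without WT 12 h replicate 3 these 3 genes also passed, at 0.36 (SE 0.05, limma adjusted p = 0.00031), 1.4 (SE 0.06, limma adjusted p = 2.8e-08) and 0.93 (SE 0.26, limma adjusted p = 0.016). Of the 35 genes, 31 had estimated line effects of opposite sign at the 2 times, of which 9 passed the threshold at both times, 2 had the same sign with the larger effect at 12 h, and 2, scaffold00145.g5108 among them, had the same sign with the larger effect at 24 h. Without that library the count was 3415, with 1931 higher and 1484 lower, including all 35. Of these 3415 genes, 1716 had estimated line effects of opposite sign, of which 602 passed at both times, 1007 had the same sign with the larger effect at 12 h, and 692 had the same sign with the larger effect at 24 h. Leaving out M2 12 h replicate 2 gave 0 genes with limma (746 at an unadjusted p under 0.05), leaving out M2 12 h replicate 1 or any single 24 h library gave 2, and leaving out WT 12 h replicate 1 or 2 gave 15 or 16. Quantile normalization gave 37 higher and 25 lower genes.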

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

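The tests on WT 12 h replicate 3 were chosen after its values had been seen, and so were those on the splits of libraries. The difference between M2 and WT differed between 24 h and 12 h by the interaction test for 35 genes with all libraries and for 3415 without WT 12 h replicate 3, and for 0 without M2 12 h replicate 2 (limma, 746 at an unadjusted p under 0.05). Scaffold00145.g5108 was picked out by the same test, with a larger rise at 24 h by 1.35 on the log2 scale, or 1.44 without WT 12 h replicate 3.

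The authors' merged column for M2 at 12 h, which entered no comparison, held a signal that its replicate columns do not. It deviated by a median of 26.5% from the best weighted mean of those columns, whereas the merged columns of WT at 12 h, WT at 24 h and M2 at 24 h deviated by 0.0095%, 0.0001% and 0.0001%. It was at 0 for 3 genes that were above 0 in replicate 1.

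WT 12 h replicate 3 correlated with its group at r = 0.715 at most. In that library 148 genes with at least 10 FPKM in the other WT 12 h libraries were at 0. A loss of reads deep enough to cause this was argued against by 245 genes with values above 0 and under 1 FPKM. A smaller loss cannot be judged from this count. It was 193 and 229 in M2 12 h replicates 1 and 2, although the worth of 1 read differed 4.08-fold between them. An exchanged label with a library present here was argued against by the highest correlation of WT 12 h replicate 3 with any, 0.757. The lowest correlation between other libraries was 0.908. An exchange with M2 12 h replicate 3 could not be tested, since the columns hold no separate values for it. A profile common to all 12 h libraries was argued against by the other 12 h libraries, which correlated with each other at 0.969 or more. The merged M2 12 h column shared the profile in part. Its deviation from the M2 12 h replicates followed that of WT 12 h replicate 3 from replicates 1 and 2. The correlation across genes was r = 0.693. Differences of the merged M2 and WT 24 h columns from the same M2 12 h replicates, not from their own, gave 0.343 and 0.402. A positive correlation is thus not particular to the merged M2 12 h column. At r = 0.865, WT 12 h replicate 3 also correlated more with the merged M2 12 h column than with any single library (0.757 at most). The merged column itself was not closest to that library. It correlated at 0.871 with WT 12 h replicates 1 and 2 and at 0.8804 to 0.8905 with the 24 h libraries. Only its correlations with the M2 12 h replicates were lower (0.826 and 0.831). Whether that column holds this library or one like it was not tested. Also open is a profile of only some 12 h libraries of both lines, which the r of 0.693 goes with. A sample from outside the series, cells of another kind in the culture and a true difference between WT cultures stay open and untested.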

How the results depend on the processing

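Counts are given in the order M2 against WT at 12 h and 24 h, 24 h against 12 h in WT and in M2, and the interaction, and the cause of a difference was not tested unless stated. The counts with all libraries were 824, 438, 1528, 1443 and 35. Other pseudocounts, other filters, no trend and robust moderation kept all 5 counts within 1.5 times. A minimum fold of 2 gave 189, 28, 323, 425 and 21, by construction fewer. Scaling to an equal sum gave 382, 164, 916, 918 and 18, FPKM as deposited gave 285 at 24 h, and quantile normalization gave 665 at 24 h and 62 for the interaction; these kept the other counts within 1.5 times. Fits of only the groups compared gave 0 (661 at an unadjusted p under 0.05, limma), 6020, 297 and 6371; for the interaction this is the fit already given. Leaving out 1 library gave 74 to 5477, 103 to 5547, 851 to 6345, 533 to 6703 and 0 to 3415, the highest each time without WT 12 h replicate 3; the lone library left in M2 at 12 h after an omission there is assumed to vary like other groups. With the replicate number as a block the counts were 198, 184, 1253, 959 and 1, and shared line effects fell from 200 to 54 genes. In that fit scaffold00145.g5108 at 12 h (0.66) and scaffold00185.g5945 (-1.51) and scaffold00080.g2595 (-1.76) at 24 h missed the threshold. Correlations of deviations in the 15 same-numbered pairs were -0.018 to 0.031. Pairs with a 12 h group cannot settle a pairing, since replicate 3 dominates the WT deviations and M2 has 2 libraries. Between WT and M2 at 24 h the correlations were -0.018 to 0.001, so no pairing by number was seen there. Chosen after seeing the data, weights per library gave 4724, 6132, 6576, 6185 and 3117, the repeated column as a library gave 2024, 683, 2165 and 186 for all but WT with time (1870), and omitting WT 12 h replicate 3 gave 3126 shared line effects and 67.4% instead of 70.3% on component 1. For the M2 against WT differences of the named genes at 12 h and 24 h, the direction held under each alternative run. Of their values, 157 stayed on their side of the threshold, 28 lost the call and 5 (DGAT1A) gained it. The 157 include 16 values at 12 h and 17 at 24 h of DGAT1A, which had no call to lose. At 24 h scaffold00185.g5945 kept its call in 11 alternatives and lost it in 9. For scaffold00080.g2595 these numbers were 12 and 8, and the pair higher in M2 kept its calls in all 20. Their time and interaction values were rerun only without WT 12 h replicate 3. Alternatives for gene lists and CA2 were not run, since IDs carry no names. Of the 10 splits of 6 libraries, 1 (the real one) gave as many genes at 24 h (438, highest other 0) and 1 in WT with time (1528, highest other 0); 10 splits are too few for a share under 0.05. Unknown read depth limits what can be said of low genes.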

Other observations

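All tests here were chosen after related values had been seen, and they use the libraries other than WT 12 h replicate 3. Genes that rose with time in WT tended to be lower in M2 than in WT, and genes that fell with time tended to be higher. Single genes departed from this: scaffold00185.g5945 and scaffold00080.g2595 fell with time in WT and were lower in M2. The time change in M2 had a slope of 0.86 on that in WT across genes (r = 0.77).

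The line effect ran against the WT time change at both times: with different WT libraries on the 2 sides, the slope was on average -0.202 at 12 h and -0.305 at 24 h. Noise of shared WT libraries, which would give a negative slope at 24 h only, was argued against there, since the 24 h slopes over these splits were -0.31 to -0.3. A trend with expression level as the whole cause was argued against by a slope nearest to 0 of -0.163 within 3 equal groups of genes by mean expression. The slope did vary with level at 24 h, with means of -0.257, -0.307 and -0.356 from the lowest group to the highest. At 12 h these means were -0.171, -0.208 and -0.196. A trend within a group is not excluded. A culture effect common to all WT 12 h libraries would give a positive slope at 12 h, and the value was -0.202, whereas one common to all WT 24 h libraries cannot be told apart from a line effect in the 24 h slope of -0.305, since no WT 24 h cultures other than these were analysed here. A hypothesis is that M2 cultures may run behind WT cultures along the same course; growth or cell density, which would bear on it, were not analysed here.

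Genes with consecutive numbers on a scaffold changed alike, with r = 0.172 over 8738 pairs for M2 against WT at 24 h and 0.165 to 0.195 in the other line and time comparisons. Chance order of the genes was argued against by 1000 shuffles, whose highest r for M2 against WT at 24 h was 0.032. A shift of whole scaffolds as the whole cause was argued against by r = 0.045 at a distance of 10 numbers in that comparison. This lay above the highest shuffled value of 0.03, so a smaller part over longer distances stays open there. For 24 h against 12 h, r at that distance was 0.003 in WT and 0.022 in M2 (highest shuffled 0.037 and 0.039). Reads shared between overlapping genes cannot be told apart from joint regulation of neighbours, since the IDs carry no coordinates and the comparisons differed. At a distance of 2, r was 0.044 for M2 against WT at 24 h (highest shuffled 0.03) and 0.066 at 12 h (0.031). With time it was 0.073 in M2 (highest shuffled 0.035) but 0.037 in WT (0.041). Whether the numbers follow gene order is not given in the sources used here.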
